A study of Homo sapiens with 9 samples.

How the data were processed

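Gene expression was measured by RNA sequencing in THP-1 cells, a human monocytic leukaemia line. Per the labels, the cells were exposed to 50 ng/mL of the phorbol ester PMA for 48 hours, which turns them into macrophage-like cells. They were then transfected by lipofection with a negative control siRNA (si-NC) or with 1 of 2 siRNAs of independent sequence against SLC40A1 (si-SLC40A1-1 and si-SLC40A1-2, here siRNA 1 and siRNA 2). Each of the 3 groups held 3 libraries, taken from the titles of the samples, which number them as biological replicates 1 to 3. Nothing in the labels says that these came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The time from transfection to harvest and the siRNA sequences were not given in the sources used here.

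The deposited table held whole-number counts of reads per gene for the 9 libraries, not normalized by the authors. Libraries were made by poly(A) selection and read as paired ends, per the labels. Reads were trimmed with cutadapt 1.18, aligned with HISAT2 2.2.1, handled with SAMtools 1.6 and counted with featureCounts 2.0.6 against the human build GRCh38, per the submitters' processing notes. Those notes give no order of use, so the role of each tool here is the one it is made for. The annotation release, the strand setting and the treatment of reads that match several places were not given in the sources used here. Genes on opposite strands of the same stretch, overlapping mitochondrial genes, and families of near-identical copies (ferritin and its pseudogenes, metallothioneins, HLA genes) are therefore uncertain to the extent that reads could be split or shared.

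The table listed 60649 gene identifiers, of which 60507 matched a symbol and 58337 matched GENCODE release 29 with the version ignored. Coordinates come from that release on GRCh38. There were 0 entries that name no gene and 0 identical pairs of libraries. Library totals ran from 57273144 to 86791388 counts. Within groups, libraries differed from each other by more than counting noise (chi-square per degree of freedom from 3.38 to 19.5 over genes), so none was taken for a second copy of another. This does not show that they came from separate cultures.

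Differential expression was tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr by group, one quasi-likelihood fit with robust estimation to all 9 libraries with group as the only term, a two-sided test for each contrast, and Benjamini-Hochberg adjustment over the 19766 genes tested. A gene was called changed at an adjusted p under 0.05. Log2 fold changes carry the standard error of that fit. Levels are given as CPM, the count scaled to the TMM-adjusted library total, as mean ± SD. The estimate of biological variation was 8.04% (coefficient of variation). The level of SLC40A1 was also compared between control and siRNA libraries by an exact permutation test.

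Lists of genes (24 in all) were tested with camera from limma 3.58.1 on voom values with a preset correlation between genes of 0.01, adjusted over the lists within each comparison. The same test with an estimated correlation, and fry, were run beside it. Unlike camera, fry does not set a list against the other genes. List members were counted as changed over all genes, and also adjusted over the list alone. The lists covered iron handling, ferroptosis suppressors and drivers, NRF2 targets, ATF4 and the unfolded protein response, metallothioneins, type I interferon response, inflammatory cytokines and chemokines, tumour-associated macrophage markers, immune checkpoints, MHC class I and class II, lysosome and phagocytosis, cholesterol synthesis, LXR targets, nuclear and mitochondrial genes of oxidative phosphorylation, glycolysis and hypoxia, cell cycle, p53 targets, and markers of macrophages, precursors, lymphocytes and other cell types. SLC40A1 was in none of them. The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The exact permutation test of SLC40A1 was not among these planned tests. 3 more lists were chosen after the data were seen and are given only at the end.

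The rule named 11 genes whatever their values: SLC40A1, FTH1, FTL, TFRC, HMOX1, GPX4, SLC7A11, ACSL4, NCOA4, HAMP and CD274. It further named, for each siRNA against the control, the 10 genes that rose and the 10 that fell most. These had to be protein-coding (or, with no known biotype, to carry an ordinary symbol), with an adjusted p under 0.05, all 3 libraries of one group above all 3 of the other, and a mean of at least 5 CPM in the higher group. By the same criteria it named the 10 rising and 10 falling genes with the largest smaller change in both comparisons, and 5 in each direction between the siRNAs. Last came up to 4 members of each list with the smallest p in the comparison described. The text leaves out some of these, and 5 genes are not reported here. It says so where it adds a gene chosen after its values were seen.

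The overlap of both comparisons with the control was set against n1 × n2 / N for independent lists and against 20 simulations of unchanged groups that shared the control libraries. Alternatives were RLE and upper-quartile scaling, no filter or a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom, fits of the 2 groups compared alone, the replicate number as a block, each library left out in turn, stricter thresholds, and fry or an estimated correlation for the lists. Chosen after the data were seen were offsets that remove each library's trend on transcript GC content (lowess span 0.3, pseudocount 0.5; 98.2% of tested genes had a GC value) and fits with 1 control library only. To look for seed effects, genes with each 7-mer in their 3' UTR were compared with the rest by the rank of their fold change. The fold changes were those with the GC trend removed, and the ranks were adjusted for the length and GC content of the UTR. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used for tables, tests and plots.

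The edgeR, DESeq2 and voom fits, camera, the GC offsets and the 7-mer test were tried on simulated data. The permutation test and fry were not. For the fits, counts were drawn for the 19766 genes, with 200 genes changed. For siRNA 1 against the control, edgeR recovered 35.8%, 55.2% and 75.8% of genes changed by 1.25, 1.5 and 2 fold, with 6 calls among unchanged genes. For siRNA 2 it recovered 38.8%, 59.7% and 75.8%, with 8 such calls. DESeq2 recovered 38.8%, 58.2% and 77.3% for siRNA 1 and 43.3%, 61.2% and 74.2% for siRNA 2, with 15 and 25 such calls. With voom the shares were 29.9%, 55.2% and 72.7%, and 32.8%, 58.2% and 74.2%, with 4 and 13 such calls. Between the siRNAs, where nothing was changed, edgeR, DESeq2 and voom made 1, 2 and 3 calls. With only the cholesterol list lowered, camera passed that list alone, with the preset and with the estimated correlation. Genes were drawn independently, so this does not show how the preset of 0.01 performs where members of a list move together. In the real data the estimated correlation of that list was 0.226 for siRNA 1 and 0.223 for siRNA 2 against the control. A GC trend put into control libraries 1 and 2 was brought from a Spearman correlation of -0.329 to -0.00461 for siRNA 1 and from -0.343 to -0.0150 for siRNA 2. The 7-mer test, run on 11838 genes, found a 7-mer shifted by -0.05 on the log2 scale and none where no shift was made.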

Results

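SLC40A1 encodes ferroportin, the only known exporter of iron from cells, and the series asks, by its title, about ferroptosis (iron-dependent death by lipid peroxidation) in macrophages and resistance to immunotherapy. RNA was counted in macrophage-like THP-1 cells transfected with a control siRNA or with siRNA 1 or siRNA 2 against SLC40A1, 3 libraries in each group. The control libraries held 86174153, 86791388 and 64133604 counts. The siRNA 1 libraries held 58062291, 58251323 and 57273144, and those of siRNA 2 held 66466402, 61802463 and 62456036. Mitochondrially encoded genes took 1.10% to 1.36% of the counts. The first 3 principal components carried 22.8%, 13.1% and 12.3% of the variance. On the first, library 1 of siRNA 1 stood at -17.5, among the control libraries (-28.1 to -13.6), while libraries 2 and 3 of siRNA 1 stood at 21.2 and 28.3. On the second, library 1 stood at -23.9, away from the control libraries (4.15 to 15.6) and from libraries 2 and 3 of siRNA 1 (13.1 and 15.3). On the third it stood at 26.5, where the control libraries lay at -11.3 to 4.73 and library 2 of siRNA 1 at 21.2. It also held the lowest SLC40A1 level of the 9 libraries, 0.239 CPM. The counts of library 1 of siRNA 1 differed from those of libraries 2 and 3 with a chi-square per degree of freedom of 15.2 and 17.7, against 3.38 between libraries 2 and 3. Control library 3 differed as much from control libraries 1 and 2 (19.5 and 17.2), and those differed from each other by 10.7.

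The target itself was weakly expressed in these cells and lay lower with both siRNAs. SLC40A1 (ENSG00000138449.11, minus strand of chromosome 2, 189560579 to 189583758, GRCh38) had 79, 70 and 52 counts in the control libraries. It had 14, 34 and 22 with siRNA 1, and 26, 32 and 26 with siRNA 2. Its level was 0.840 ± 0.0658 CPM (SD, n = 3) in the control, 0.406 ± 0.176 CPM with siRNA 1 and 0.443 ± 0.0708 CPM with siRNA 2, which is 48.4% and 52.7% of the control. The highest siRNA library stood at 0.591 CPM and the lowest control library at 0.802 CPM. The control differed from the 6 siRNA libraries together (exact permutation test, two-sided p = 0.0119, the smallest that 84 splits can give). The permutation test was not among the planned tests. In the edgeR fit the log2 fold change was -1.05 ± 0.29 (SE) with siRNA 1 (adjusted p = 0.0532) and -0.92 ± 0.29 with siRNA 2 (adjusted p = 0.0560), so neither call passed over all genes. SLC40A1 passed with siRNA 1 without control library 3 (adjusted p = 0.0457). With siRNA 2 it passed without siRNA 1 library 1 (0.0176) and without siRNA 1 library 2 (0.0462). In the other fits with 1 library left out it did not pass, and the edgeR adjusted p reached 0.222 and 0.191 without control library 1. Both siRNAs passed with no filter on low counts (0.0136 and 0.0316) and with the replicate number as a block (0.0137 and 0.0245). They also passed with the trend on GC content removed (0.0429 and 0.0456), a fit chosen after the data were seen. In the fit of 2 groups alone siRNA 2 passed (0.0177) and siRNA 1 did not (0.0888). Between the siRNAs the log2 fold change of SLC40A1 was 0.12 (95% interval -0.53 to 0.77; edgeR adjusted p = 0.974), so a difference within that interval stays open.

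**Figure D1:**
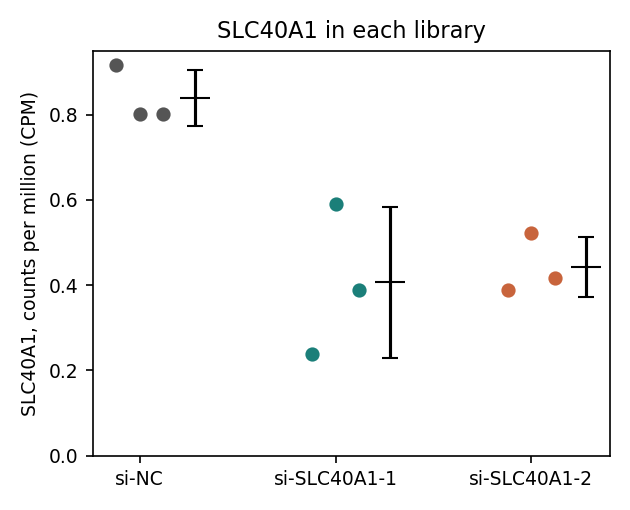
Level of SLC40A1 in CPM (count scaled to library size) in each library (points, by group), with the mean and SD of each group of 3 beside them (bars). All 6 siRNA libraries, at 0.591 CPM or less, lie under the 3 control libraries, at 0.802 CPM or more.

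Control libraries 1 and 2 stood apart from the other 7 in GC-rich genes. They were also the deepest, at 86174153 and 86791388 counts against 57273144 to 66466402 in the other 7. From the lowest to the highest quintile of genes by transcript GC content, the median level of control libraries 1 and 2 climbed by 0.147 and 0.217 on the log2 scale. The level changed by -0.109 in control library 3 and by -0.081 to -0.023 in the siRNA libraries. Levels were set against each gene's mean over all 9 libraries, so the climb of control libraries 1 and 2 itself lowers the slopes of the others. Across genes, which are not independent replicates, the fold change followed GC content with a Spearman correlation of -0.280 for siRNA 1, -0.296 for siRNA 2 and -0.0365 between the siRNAs. Genes that rose had a median GC content of 43.3% with siRNA 1 and 43.0% with siRNA 2, and genes that fell 54.9% and 55.2%, where protein-coding genes as a whole had 48.5%. Values with this trend removed are given beside each gene group whose test passed.

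**Figure D2:**
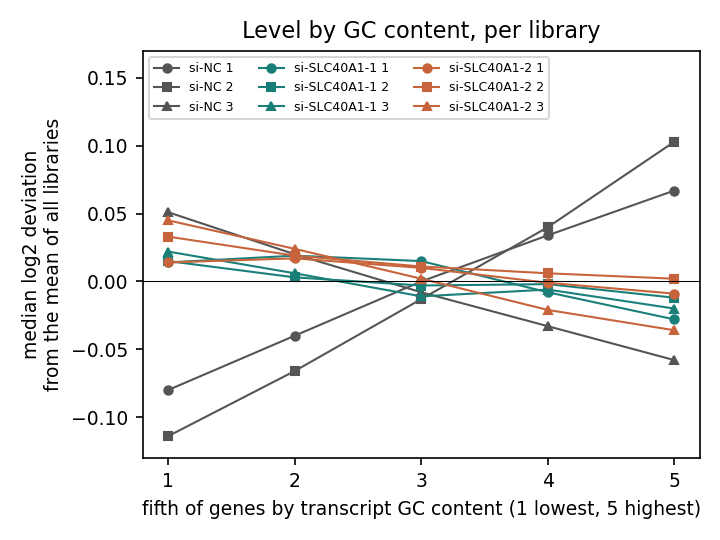
Median log2 deviation of a library from the mean of all 9 (vertical axis) in each quintile of genes by transcript GC content (horizontal axis), 1 line per library, coloured by group. Relative to that mean, control libraries 1 and 2 climb from the lowest to the highest quintile by 0.147 and 0.217. The other 7 libraries fall, in part because the mean includes the libraries that climb.

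Each gene named here among the largest changes with siRNA 1 moved by less than 2 fold. These are the largest within the naming rule, and called genes that did not meet it could change more. Integrin beta 8 (ITGB8) rose by 0.70 ± 0.14 on the log2 scale (SE, n = 3 per group), the myeloid lectin receptor CLEC5A by 0.55 ± 0.12 and the tryptophan-degrading enzyme IDO1 by 0.51 ± 0.09. The inositol monophosphatase IMPA2 fell by 0.73 ± 0.13, the mRNA decay factor ZFP36 (tristetraprolin) by 0.61 ± 0.08, the Notch target HES1 by 0.54 ± 0.13 and the lipid droplet protein HILPDA by 0.53 ± 0.06. The kinetochore gene ZWINT rose by 0.50 ± 0.11, LAMP3 by 0.49 ± 0.10, the amino acid transporter SLC16A10 by 0.48 ± 0.12, the nucleotide sugar transporter SLC35A3 by 0.47 ± 0.11 and the protease inhibitor TFPI2 by 0.44 ± 0.07. CCM2L fell by 0.67 ± 0.10, KAZALD1 by 0.61 ± 0.14, TOX2 and CYFIP2 by 0.59 each and the Wnt cofactor BCL9 by 0.54 ± 0.10.

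The edgeR test called 620 genes with siRNA 1, of which 314 rose and 306 fell, with a median fold of 1.23; 26 changed by 2 fold or more. An unadjusted p under 0.05 was met by 4143 genes, where 988.3 would be expected by chance, and the groups did not overlap in 19.6% of tested genes, where chance gives 10% for 3 against 3. The count rested on single libraries: it was 23, 16 and 2203 without control library 1, 2 or 3, 2987, 24 and 19 without siRNA 1 library 1, 2 or 3, and 298 and 149 without siRNA 2 library 2 or 3. A fit of these 2 groups alone gave 112, and of the 77 genes called here that the naming rule picked, 5 passed in each of the 9 fits with 1 library left out, CCM2L, DDIT4, HILPDA and ZNF267 among them. Of 584 tested genes in the lists, 55 were called. That count was 3, 2 and 129 without control library 1, 2 or 3, 177, 3 and 2 without siRNA 1 library 1, 2 or 3, and 30 and 16 without siRNA 2 library 2 or 3.

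Of 24 cholesterol synthesis genes tested, 6 fell with siRNA 1 (19 adjusted over the list alone) and the median log2 fold change was -0.18 (camera adjusted p = 1.43e-10; adjusted p = 0.227 with an estimated correlation). The farnesyl diphosphate synthase FDPS fell by 0.25 ± 0.05, the lanosterol demethylase CYP51A1 by 0.35 ± 0.09, and the sterol reductase DHCR7 by 0.29 ± 0.06. With the GC trend removed the median was -0.17 (adjusted p = 9.70e-12). The list also passed with fry (adjusted p = 0.0175). The members that fell numbered 13, 11 and 3 without control library 3, siRNA 1 library 1 or siRNA 2 library 2. By edgeR they numbered 0 without control library 1 or 2, siRNA 1 library 2 or 3 or siRNA 2 library 3, where 13 to 19 had an unadjusted p under 0.05. Among LXR targets and lipid handling genes (23 tested), lipoprotein lipase (LPL) rose by 0.37 ± 0.07 while HILPDA and the fatty acid synthase FASN (-0.31 ± 0.07) fell, with 4 up and 3 down adjusted over the list alone (camera adjusted p = 0.705). Nuclear genes of oxidative phosphorylation were higher as a group: 35 of 40 had a positive value and the median was 0.08 (camera adjusted p = 0.00112; adjusted p = 0.320 with an estimated correlation; 0.000519 with the GC trend removed). Only the succinate dehydrogenase subunit SDHD passed over all genes (0.26 ± 0.06), and 3 members rose adjusted over the list alone. With fry this list passed (adjusted p = 0.0175). Of 13 mitochondrially encoded genes, MT-ND3 (0.39 ± 0.09) and MT-CO3 (0.33 ± 0.07) rose, with 3 up and 1 down adjusted over the list alone and a median of -0.18 (camera adjusted p = 0.156). That list passed downward without control library 3 (0.0447) or siRNA 1 library 1 (0.0407).

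Of 37 type I interferon response genes tested, 5 rose with siRNA 1 (12 adjusted over the list alone), the median was 0.08 and 28 were positive (camera adjusted p = 2.99e-06; adjusted p = 0.180 with an estimated correlation; 5.97e-05 with the GC trend removed). By edgeR 0 rose without control library 1 or 2 or siRNA 1 library 2 or 3, where 10 to 15 had an unadjusted p under 0.05. Without control library 3 or siRNA 1 library 1, 8 and 9 rose, and without siRNA 2 library 2 or 3, 3 rose. HERC5, an ISG15 ligase, rose by 0.30 ± 0.06, the antiviral enzyme RSAD2 (viperin) by 0.25 ± 0.05, ISG20 by 0.24 ± 0.05 and IFIT1 by 0.20 ± 0.05. Of 36 inflammatory cytokines and chemokines, CXCL1 (0.38 ± 0.09), CXCL11 (0.27 ± 0.05) and the costimulatory gene CD86 (0.28 ± 0.07) rose and TNFAIP3, which restrains NF-kB, fell by 0.18 ± 0.04. Adjusted over the list alone 7 rose and 2 fell, with a median of 0.13 (camera adjusted p = 0.00921; adjusted p = 0.227 with an estimated correlation; 0.0209 with the GC trend removed). Of 16 MHC class I genes, beta-2 microglobulin (B2M, 0.19 ± 0.05), PSME2 and ERAP1 rose (4 adjusted over the list alone, median 0.09, camera adjusted p = 0.0227; adjusted p = 0.227 with an estimated correlation; 0.00794 with the GC trend removed). The class I call ended without control library 3 (0.0682) or siRNA 1 library 1 (0.142). With fry the interferon (adjusted p = 0.0139), cytokine (0.0240) and class I (0.0175) lists passed upward. Of 10 MHC class II genes, HLA-DQA1, at 2.03 CPM with siRNA 1, rose by 0.69 ± 0.18 and was the 1 member that passed adjusted over the list alone (camera adjusted p = 0.283).

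Markers of macrophage differentiation were lower as a group with siRNA 1: of 27 tested, the integrins ITGAM (-0.28 ± 0.05) and ITGB2 (-0.19 ± 0.05) and the transcription factor MAF (-0.24 ± 0.05) fell, and TLR4 rose by 0.27 ± 0.05, the same 3 and 1 as adjusted over the list alone in number. The median was -0.10 (camera adjusted p = 0.0153; adjusted p = 0.553 with an estimated correlation). This call ended with fry (0.258), with the GC trend removed (0.116), without control library 1 (0.0926) and without siRNA 1 library 3 (0.0581). Against control library 3 alone the list pointed up by camera, with a median of -0.01. Among 28 markers of alternatively activated or tumour-associated macrophages, fibronectin (FN1) rose by 0.31 ± 0.06 and the IL-4 receptor IL4R fell by 0.19 ± 0.05. Adjusted over the list alone 5 rose and 3 fell (camera adjusted p = 0.960, downward), and the list pointed up against control library 3 alone. Among 28 immune checkpoint genes, HAVCR2 (TIM-3; 0.23 ± 0.04) and IDO1 rose and PDCD1LG2 (PD-L2; -0.27 ± 0.07) fell, with 6 up and 4 down adjusted over the list alone (camera adjusted p = 0.230; 0.0375, upward, with fry). CD274, which encodes PD-L1, had a log2 fold change of 0.15 ± 0.06 (edgeR adjusted p = 0.144). Among 37 lysosome and phagocytosis genes, LAMP2 (0.19 ± 0.05) and the Fc receptor FCGR3A (0.25 ± 0.06) rose, 3 up and 1 down adjusted over the list alone (camera adjusted p = 0.154, and 0.0215 without control library 1).

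Of 32 iron handling genes, the ferritin autophagy receptor NCOA4 (0.24 ± 0.05), the zinc and iron importer SLC39A8 (0.26 ± 0.07) and the iron chaperone PCBP2 (0.26 ± 0.06) rose with siRNA 1, and the mitochondrial iron importer SLC25A37 fell by 0.18 ± 0.04. Adjusted over the list alone 5 rose and 5 fell (camera adjusted p = 0.520). The ferritin subunits FTH1 (-0.02 ± 0.06) and FTL (0.03 ± 0.05), the transferrin receptor TFRC (0.21 ± 0.07, edgeR adjusted p = 0.0797) and the haem oxygenase HMOX1 (0.06 ± 0.04) did not pass. HAMP, which encodes the ferroportin ligand hepcidin, lay at 0.150 CPM in the control and could not be judged at this depth. Among 26 genes listed as ferroptosis suppressors, CISD2 rose by 0.32 ± 0.08 and DHCR7 fell. Adjusted over the list alone 5 rose and 1 fell (camera adjusted p = 0.493). The role of DHCR7 in ferroptosis was not tested, so its fall was not read as the loss of a suppressor. GPX4, which reduces lipid peroxides, had 0.12 ± 0.06, and the cystine importer SLC7A11 had 0.33 ± 0.11 (edgeR adjusted p = 0.114). Among 27 ferroptosis drivers, EMP1 (0.23 ± 0.05) and NCOA4 rose and ATG7 (-0.22 ± 0.06) and the desaturase FADS1 (-0.23 ± 0.06) fell, with 5 up and 3 down adjusted over the list alone (camera adjusted p = 0.202); the lipid ligase ACSL4 had -0.01 ± 0.05. Of 8 metallothionein and zinc export genes, their regulator MTF1 fell by 0.22 ± 0.05, alone in the list also when adjusted over the list alone (camera adjusted p = 0.393).

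Of 30 NRF2 targets edgeR called 0 over all genes with siRNA 1, and 5 rose adjusted over the list alone. At an unadjusted p under 0.05, 8 rose, and DESeq2 called 6 and voom 0 (median 0.06, camera adjusted p = 0.0153; adjusted p = 0.565 with an estimated correlation; 0.00312 with the GC trend removed). The NRF2 call ended with fry (0.258), without control library 3 (0.0520), siRNA 1 library 2 (0.118) or siRNA 1 library 3 (0.133). Of 38 cell cycle genes PCNA rose by 0.35 ± 0.09, also the 1 call adjusted over the list alone, with a list median of 0.14 (camera adjusted p = 0.0209; adjusted p = 0.565 with an estimated correlation; 0.0230 with the GC trend removed). The cell cycle call ended with fry (0.272), without control library 2 (0.117), siRNA 1 library 2 (0.118) or siRNA 1 library 3 (0.133). Of 32 ATF4 and unfolded protein response genes, the chaperone HSPA5 rose by 0.27 ± 0.06 and DDIT4 (-0.44 ± 0.06), PHGDH and HERPUD1 fell (2 up and 4 down adjusted over the list alone; camera adjusted p = 0.960). The median of that list was 0.01, its mean -0.02 and its test pointed down. Of 31 p53 targets and cell death genes, 3 rose, ZMAT3 (0.37 ± 0.08) and PMAIP1 among them, with 6 up and 2 down adjusted over the list alone (camera adjusted p = 0.0569, upward with a median of 0.07 but a mean of -0.01; 0.0244 with fry and 0.0427 without control library 3). Of 34 glycolysis and hypoxia genes the aldolases ALDOA (-0.25 ± 0.06) and ALDOC (-0.30 ± 0.07) fell, the same 2 in number as adjusted over the list alone, while the list pointed up (camera adjusted p = 0.0815; 0.00891 without control library 2 and 0.00222 without siRNA 1 library 1). Among markers of other cells, edgeR called 0 of 15 precursor, 0 of 8 lymphocyte and 0 of 7 epithelial, fibroblast, endothelial and erythroid genes, and adjusted over the list alone 1 of the last group fell. At an unadjusted p under 0.05 these lists held 3, 0 and 2 genes, DESeq2 called 1, 0 and 1 of them and voom 0 of any (camera adjusted p = 0.579, 0.705 and 0.240).

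The genes named for the largest changes with siRNA 2 are again the largest within the naming rule, and other called genes could change more. Among them the chemokine gene CXCL11 rose by 0.57 ± 0.05 on the log2 scale (SE, n = 3 per group, edgeR adjusted p = 7.57e-06). IDO1 rose by 0.57 ± 0.09, the double-stranded RNA sensor TLR3 by 0.53 ± 0.10 and the nucleolar protein gene NOLC1 by 0.50 ± 0.06. The platelet-derived growth factor gene PDGFB fell by 0.97 ± 0.09 (edgeR adjusted p = 7.57e-06), the transcription factor KLF2 by 0.77 ± 0.11, ZFP36 by 0.68 ± 0.08 and BCL3, an atypical member of the I-kappa-B family, by 0.68 ± 0.07. The collagenase MMP13 rose by 0.68 ± 0.12, CLEC5A and KLHL11 by 0.50 each, MT-ATP8 and PCDHB2 by 0.48 each and ZMAT3 by 0.47 ± 0.08. TMEM8B fell by 0.73 ± 0.12, LRFN1 by 0.66 ± 0.17, IMPA2 by 0.65 ± 0.13, HES1 by 0.63 ± 0.13, HILPDA by 0.60 ± 0.06 and DIPK1B by 0.56 ± 0.14.

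The edgeR test called 1284 genes with siRNA 2, of which 647 rose and 637 fell, with a median fold of 1.21; 34 changed by 2 fold or more. With upper-quartile scaling 502 rose and 820 fell. An unadjusted p under 0.05 was met by 4449 genes, and the groups did not overlap in 27.4% of tested genes (10% by chance). The count was 371, 269 and 2502 without control library 1, 2 or 3, 2334 without siRNA 1 library 1, and 775, 167 and 254 without siRNA 2 library 1, 2 or 3. Of the 88 genes called here that the naming rule picked, 32 passed in each of the 9 fits with 1 library left out, CXCL11, PDGFB, HILPDA, BCL3 and FDPS among them. Of the 584 tested genes in the lists 99 were called, and 47, 35, 24 and 36 without control library 1, control library 2, siRNA 2 library 2 or siRNA 2 library 3.

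Of 24 cholesterol synthesis genes tested, 17 fell with siRNA 2 (19 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 9.23e-14; adjusted p = 0.149 with an estimated correlation). FDPS fell by 0.37 ± 0.05, the sterol reductase HSD17B7 by 0.36 ± 0.07 and the acetoacetyl-CoA thiolase ACAT2 by 0.32 ± 0.06. With the GC trend removed the median was -0.27 (adjusted p = 6.41e-15). The list also passed with fry (adjusted p = 0.00548). The number of members that fell was 8, 10, 3 and 11 without control library 1, control library 2, siRNA 2 library 2 or siRNA 2 library 3. Among 23 LXR targets and lipid handling genes, HILPDA, ANGPTL4 (-0.36 ± 0.06), FASN (-0.29 ± 0.07) and SREBF1 (-0.21 ± 0.06) fell and FABP5 (0.25 ± 0.06) and SMPDL3A rose, the same 4 and 2 in number as adjusted over the list alone (camera adjusted p = 0.285). Of 40 nuclear genes of oxidative phosphorylation, 8 rose (12 adjusted over the list alone) and 39 were positive. The median was 0.12 (camera adjusted p = 9.65e-10; adjusted p = 0.149 with an estimated correlation; 1.16e-10 with the GC trend removed). The members that rose numbered 2 without control library 1 or 2, 5 without siRNA 1 library 2 and 3 without siRNA 2 library 1. By edgeR they numbered 0 without siRNA 2 library 2 or 3, where 13 and 16 had an unadjusted p under 0.05. Examples were the succinate dehydrogenase subunits SDHD (0.29 ± 0.06) and SDHB (0.23 ± 0.05), the Rieske protein UQCRFS1 (0.22 ± 0.05) and the ATP synthase subunit ATP5F1B (0.19 ± 0.04). Of 13 mitochondrially encoded genes, MT-ATP8, MT-ND3 (0.46 ± 0.09), MT-ND2 (0.43 ± 0.10) and MT-CO3 (0.38 ± 0.07) rose, also 4 adjusted over the list alone, with a median of 0.09 (camera adjusted p = 0.00149; adjusted p = 0.501 with an estimated correlation; 0.0113 with the GC trend removed). The mitochondrial call ended with fry (0.138) and without control library 3 (0.163). The list of nuclear genes passed with fry (adjusted p = 0.00288).

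**Figure D3:**
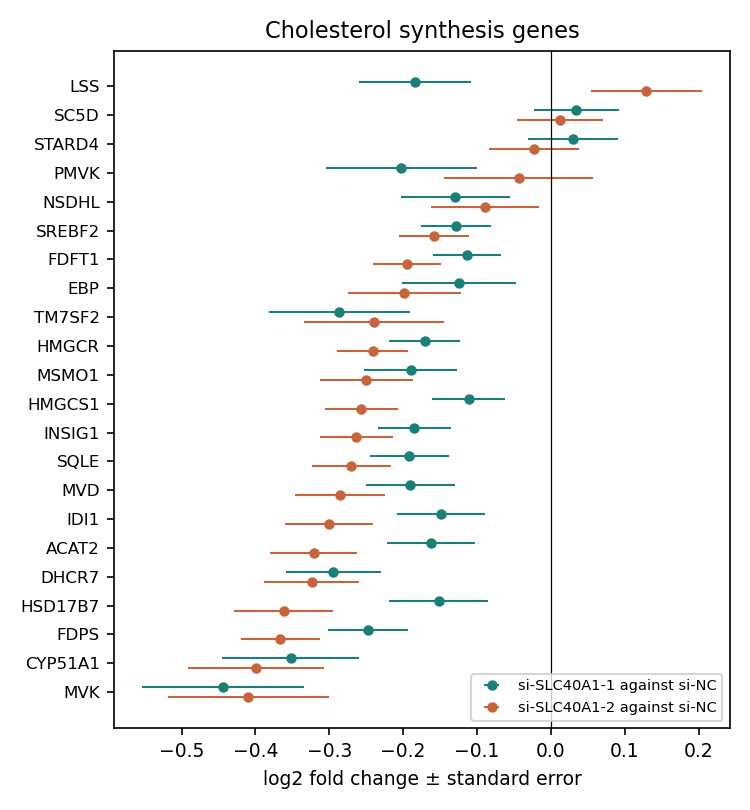
Log2 fold change against the control with its standard error (horizontal axis) for 22 of the 24 tested cholesterol synthesis genes (vertical axis), siRNA 1 in green and siRNA 2 in orange, 3 libraries per group. With each siRNA 20 of the 22 values drawn lie below 0, and the medians of all 24 are -0.18 and -0.26.

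Of 16 MHC class I genes, the proteasome activator PSME2 (0.27 ± 0.05), B2M (0.24 ± 0.05) and the peptidase ERAP1 (0.24 ± 0.05) rose with siRNA 2, 7 adjusted over the list alone, with a median of 0.15 (camera adjusted p = 0.0137; adjusted p = 0.165 with an estimated correlation; 0.00284 with the GC trend removed). The call ended without control library 3 (0.0522). With fry the list passed (adjusted p = 0.00548). Of 10 MHC class II genes, HLA-DQA1 rose by 0.64 ± 0.18 and its transactivator CIITA fell by 0.35 ± 0.10 (2 up and 1 down adjusted over the list alone; camera adjusted p = 0.285). Of 37 type I interferon response genes, CXCL10 (0.31 ± 0.05), IFIT1 (0.24 ± 0.05) and ISG20 (0.21 ± 0.05) rose, 4 adjusted over the list alone, with a median of 0.01 (camera adjusted p = 0.368). Of 36 cytokine and chemokine genes, CXCL9, CXCL10, CXCL11 and CD86 rose, and CXCL2, LIF and the NF-kB inhibitors NFKBIA (-0.24 ± 0.05) and TNFAIP3 (-0.28 ± 0.04) fell, also 4 and 4 adjusted over the list alone (camera adjusted p = 0.164). Among 28 immune checkpoint genes IDO1 rose, with 6 up and 3 down adjusted over the list alone, and CD274 had 0.19 ± 0.06 (edgeR adjusted p = 0.0517). The median of that list was 0.02, its mean -0.01 and its test pointed up (camera adjusted p = 0.383). Of 28 tumour-associated macrophage markers edgeR called 0, also adjusted over the list alone, where 7 met an unadjusted p under 0.05, DESeq2 called 2 and voom 1 (camera adjusted p = 0.383). Of 27 macrophage differentiation markers, CD14, LYZ and TLR4 (0.22 ± 0.05) rose and 5 fell, among them MAF (-0.38 ± 0.05), ITGAM (-0.30 ± 0.05), ITGAX (-0.27 ± 0.05) and CSF1, with 5 up and 9 down adjusted over the list alone (camera adjusted p = 0.0827). That list passed downward without control library 3 (0.00871), siRNA 1 library 1 (0.0287) or siRNA 2 library 1 (0.0443). Of 37 lysosome and phagocytosis genes SCARB2 (0.21 ± 0.05) rose and FCGR2B (-0.17 ± 0.05) fell, also when adjusted over the list alone (camera adjusted p = 0.187; 0.0447 without control library 1). CD14, LYZ, CSF1, CXCL9, CXCL2, LIF and SMPDL3A were named after their values were seen.

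Of 32 iron handling genes, TFRC (0.25 ± 0.07, edgeR adjusted p = 0.0288), NCOA4 (0.22 ± 0.05) and SLC39A8 (0.30 ± 0.07) rose with siRNA 2. SLC25A37 (-0.28 ± 0.04), PCBP1 (-0.30 ± 0.06), SLC25A28 and the phagosomal metal transporter SLC11A1 fell, the last 2 named after their values were seen. Adjusted over the list alone 5 rose and 5 fell (camera adjusted p = 0.518). FTH1 (-0.07 ± 0.06), FTL (-0.02 ± 0.05), HMOX1 (-0.11 ± 0.04), GPX4 (0.05 ± 0.06), SLC7A11 (0.13 ± 0.11) and ACSL4 (0.09 ± 0.05) did not pass, with edgeR adjusted p of 0.139 or more, and HAMP could not be judged at 0.135 CPM. Of 26 genes listed as ferroptosis suppressors, CISD1 (0.31 ± 0.07), CISD2 (0.32 ± 0.08) and the glutathione synthesis gene GCLC (0.28 ± 0.07) rose and DHCR7 (-0.32 ± 0.06) fell. Adjusted over the list alone 4 rose and 3 fell (camera adjusted p = 0.960). The fall of DHCR7 was again not read as the loss of a suppressor. Of 27 ferroptosis drivers, the oxidase subunit CYBB (0.23 ± 0.05), EMP1 (0.20 ± 0.05), PEBP1, NCOA4 and TFRC rose and ATG7 (-0.24 ± 0.06) and FADS1 fell, 8 up and 3 down adjusted over the list alone (camera adjusted p = 0.162; 0.0363, upward, with fry); PEBP1 was named after its value was seen.

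Of 32 ATF4 and unfolded protein response genes, DDIT4 (-0.47 ± 0.06), ATF3 (-0.29 ± 0.05), SESN2 (-0.23 ± 0.05) and 4 others fell with siRNA 2 and HSPA5 (0.34 ± 0.06) and DNAJC3 rose, 5 up and 10 down adjusted over the list alone (camera adjusted p = 0.681, downward with a mean of -0.03 but a median of 0.03). Of 30 NRF2 targets GCLC and PRDX1 rose, the same 2 in number as adjusted over the list alone (camera adjusted p = 0.699, upward with a mean of 0.02 but a median of -0.01). Of 31 p53 targets, ZMAT3, PMAIP1 (0.38 ± 0.06) and AEN (0.32 ± 0.08) rose and DDB2 (-0.26 ± 0.06) and CDKN1A fell, also 3 and 2 adjusted over the list alone (camera adjusted p = 0.383, upward with a median of 0.02 but a mean of -0.03). Of 38 cell cycle genes CENPF rose by 0.30 ± 0.09, but not adjusted over the list alone (camera adjusted p = 0.219). ALDOA (-0.30 ± 0.06) and ALDOC (-0.29 ± 0.07) fell among 34 glycolysis and hypoxia genes, with 1 up and 2 down adjusted over the list alone (camera adjusted p = 1.00, upward, with a median of -0.01 and a mean of -0.01). MTF1 fell by 0.20 ± 0.05 among 8 metallothionein and zinc export genes, also adjusted over the list alone (camera adjusted p = 0.641). Of 15 precursor markers CD38 (0.28 ± 0.05) rose and MYC (-0.27 ± 0.07) and RUNX3 (-0.24 ± 0.05) fell, likewise when adjusted over the list alone (camera adjusted p = 0.518). Of the 7 epithelial, fibroblast, endothelial and erythroid markers VWF, at 2.42 CPM with siRNA 2, fell by 0.57 ± 0.14, with 2 down adjusted over the list alone (camera adjusted p = 0.209). edgeR, DESeq2 and voom called 0 of 8 lymphocyte markers, as did an unadjusted p under 0.05 (camera adjusted p = 0.627). DNAJC3 and CDKN1A were named after their values were seen.

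Both siRNAs changed 398 genes in the same direction, with 0 called in opposite directions. The genes that rose with both included IDO1, CLEC5A, KLHL11, ZWINT, the splicing factor SRSF6 (0.44 and 0.42), the zinc finger gene ZNF267 (0.42 and 0.43), BRD8 (0.40 and 0.41), CENATAC (0.39 and 0.46) and MT-ND3. The genes that fell with both included IMPA2, ZFP36, TMEM8B (-0.58 and -0.73), HES1, HILPDA, CCM2L (-0.67 and -0.53), PDGFB (-0.52 and -0.97), the gasdermin GSDMB (-0.50 and -0.48), the reductase CYB5R2 (-0.47 and -0.56) and CYFIP2 (-0.59 and -0.46). NCOA4, SLC39A8, HSPA5, IFIT1 and B2M rose, and FDPS, DHCR7, DDIT4, MAF and SLC25A37 fell, in both comparisons.

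Of these genes 204 rose and 194 fell (162 and 240 with upper-quartile scaling), where independent lists of these sizes would share 10.3 and 9.86. Simulated unchanged groups set against the same control libraries shared at most 2 calls in 20 simulations. Each gene was drawn independently there, with no GC trend or other deviation of a whole library. The simulated values are therefore not the chance level for libraries that deviate in such ways, as these do. The shared genes were 64.2% of the siRNA 1 calls and 31.0% of the siRNA 2 calls. Over all tested genes, which are not independent, 77.4% had the same sign (66.0% simulated) and the correlation of fold changes was 0.634 (0.475 simulated). The covariance was 0.0679 against 0.0297 simulated, a difference of 0.0382. The 3 control libraries cannot give each siRNA 2 of its own, so part of the excess over the simulated values may come from the shared controls. With each siRNA set against a different single control library the covariance was 0.0198 to 0.0418 in the 6 pairings. The shared count was 21, 14 and 1552 without control library 1, 2 or 3, 1278, 22 and 17 without siRNA 1 library 1, 2 or 3, and 263, 73 and 68 without siRNA 2 library 1, 2 or 3.

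**Figure D4:**
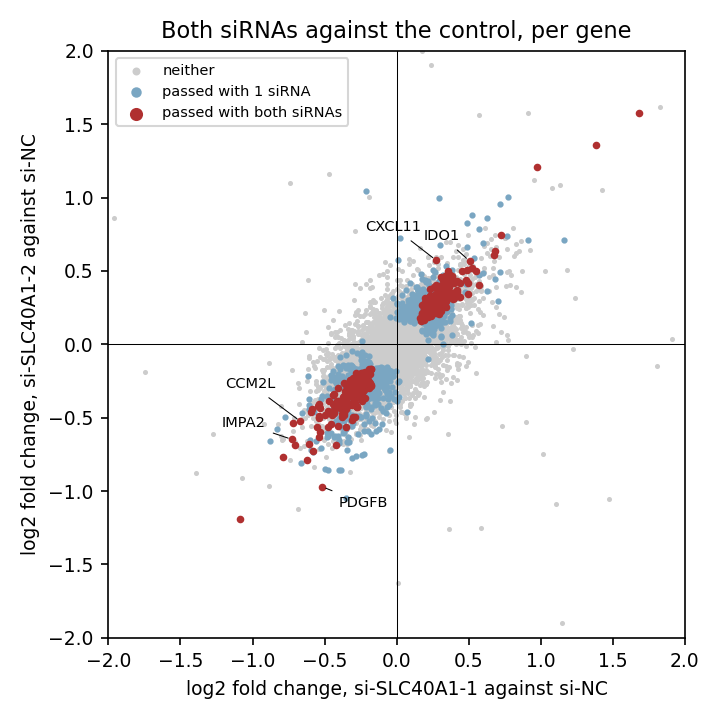
Log2 fold change against the control of each gene at 1 CPM or more in the higher group (14223 genes), siRNA 1 on the horizontal and siRNA 2 on the vertical axis, with 38 genes outside the axes of ±2 not shown. Colours give genes past an edgeR adjusted p of 0.05 with both siRNAs, 1 or neither, and the genes that passed with both have the same sign in both.

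Set against each other, the siRNAs differed in few genes. With siRNA 2, the creatine synthesis enzyme GATM (0.31 ± 0.05) and CXCL11 (0.30 ± 0.05) were higher than with siRNA 1. The phospholipid acyltransferase LPCAT1 (-0.75 ± 0.12), the phosphatase DUSP1 (-0.39 ± 0.07), OTOF (-0.37 ± 0.06) and the proteoglycan SDC2 (-0.32 ± 0.05) were lower. Each of these had an edgeR adjusted p of 0.0336. STAG3L1, an unprocessed pseudogene named after its value was seen, was higher by 1.26 ± 0.17 (edgeR adjusted p = 0.00994), and its reads may be shared with its parent family.

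The edgeR test called these 7 genes, 3 higher and 4 lower, with 1407 at an unadjusted p under 0.05 (988.3 by chance) and groups apart in 13.7% of genes (10% by chance). DESeq2 called 26 and voom 0. Without a library the count was 11 and 4 (control 1 and 2), 279, 3 and 0 (siRNA 1 libraries 1, 2 and 3) and 2, 1 and 0 (siRNA 2 libraries 1, 2 and 3). Of the 6 named genes called, 0 passed in each of the 9 fits with 1 library left out.

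Of the 24 lists, 7 differed between the siRNAs by camera, and all 7 calls ended with fry (adjusted p from 0.0692 to 0.658). With siRNA 2, mitochondrially encoded genes were higher than with siRNA 1 in 13 of 13 members, with a median of 0.30 (camera adjusted p = 4.93e-14; adjusted p = 0.0788 with an estimated correlation; 4.66e-11 with the GC trend removed). Nuclear genes of oxidative phosphorylation were also higher (median 0.06, camera adjusted p = 3.61e-05; adjusted p = 0.215 with an estimated correlation; 1.83e-05 with the GC trend removed). Type I interferon response genes were lower (median -0.07, 3 of 37 positive, camera adjusted p = 1.82e-07; adjusted p = 0.0788 with an estimated correlation; 3.62e-08 with the GC trend removed). Cholesterol synthesis genes were lower too (median -0.07, camera adjusted p = 0.00373; adjusted p = 0.660 with an estimated correlation; 0.000993 with the GC trend removed), as were LXR targets (median -0.07, camera adjusted p = 0.00532; adjusted p = 0.137 with an estimated correlation; 0.00813 with the GC trend removed). NRF2 targets (median -0.06, camera adjusted p = 0.00419; adjusted p = 0.660 with an estimated correlation; 0.00547 with the GC trend removed) and glycolysis genes (median -0.03, camera adjusted p = 0.00746; adjusted p = 0.694 with an estimated correlation; 0.0181 with the GC trend removed) were lower as well. Adjusted over the list alone, 4 mitochondrially encoded genes passed upward, and 1 member passed in each of the interferon (upward), cholesterol (upward), LXR (downward) and NRF2 (downward) lists. The cholesterol call ended without siRNA 1 library 1 (0.146) or siRNA 2 library 2 (0.185), and the LXR call without siRNA 1 library 1 (0.146). The NRF2 call ended without siRNA 1 library 2 (0.207) or 3 (0.330). The glycolysis call ended without siRNA 1 library 2 (0.224) or 3 (0.348) or siRNA 2 library 1 (0.333). Cell cycle genes (camera adjusted p = 0.289) passed downward without siRNA 1 library 1 (0.000592). The other 17 lists did not pass, and in 7 of them, iron handling, ferroptosis drivers, MHC class I, MHC class II, lysosome, macrophage differentiation and lymphocyte markers, the median, the mean and the test did not share 1 sign.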

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

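The tests in this part were set before their results were seen, with 2 exceptions in the 7-mer test. These were the bound of 0.1 on the smallest detectable shift and the use of fold changes with the GC trend removed. A difference between the siRNAs brought 6 genes and 7 gene lists to attention. GATM (0.31) and CXCL11 (0.30) were higher with siRNA 2 than with siRNA 1, and LPCAT1 (-0.75), DUSP1 (-0.39), OTOF (-0.37) and SDC2 (-0.32) were lower, by log2 fold change in the edgeR fit. Relative to the control, DUSP1 and OTOF fell with siRNA 2 (-0.39 and -0.36) and had 0.00 and 0.02 with siRNA 1. SDC2 rose with siRNA 1 (0.22) and had -0.10 with siRNA 2, and LPCAT1 had 0.37 and -0.39 with neither past the threshold. By camera, the lists that were higher with siRNA 2 were mitochondrially encoded genes (adjusted p = 4.93e-14) and nuclear genes of oxidative phosphorylation (3.61e-05). Those that were lower were type I interferon response (1.82e-07), cholesterol synthesis (0.00373), NRF2 targets (0.00419), LXR targets (0.00532) and glycolysis (0.00746). With an estimated correlation 0 of these 7 lists passed, with adjusted p from 0.0788 to 0.694.

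The siRNAs carry different sequences, and seed-dependent silencing of other transcripts could make them differ, which would lower genes with a matching 7-mer in the 3' UTR. Of 16218 7-mers tested over 11838 genes, 0 passed the Bonferroni threshold between the siRNAs in either direction (largest z 3.52, threshold 4.67). By the spread of the fold changes, a shift of 0.0118 on the log2 scale would put a 7-mer in 1149 genes at the threshold, not safely past it. CATGATG (1458 genes), with a median difference of -0.0107, reached only z = -3.28. In simulated data, with fold changes permuted across genes, a shift of -0.05 for 1 chosen 7-mer was found. A seed effect of that size in a 7-mer held by about 1149 genes, the median, was argued against for the difference between the siRNAs. Smaller shifts stay open, as do shifts of rarer 7-mers, which were tested down to 50 genes and need a larger shift to pass. Longer matches to single transcripts stay open, as the siRNA sequences were not given in the sources used here. A biological difference between the siRNAs was not tested.

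Regrouping the libraries gave no share under 0.05 for the single comparisons, since 3 against 3 makes 10 splits. With fits of 2 groups alone, siRNA 1 against the control called 112 genes and the highest other split 86, so 1 of 10 splits gave as many. The split with 86 exchanged library 1 of siRNA 1 for control library 3. For siRNA 2 the values were 1865 and 3, again 1 of 10. Between the siRNAs the real split called 5 and the highest other 623, so 2 of 10 gave as many. That split set library 1 of siRNA 1 and libraries 1 and 3 of siRNA 2 against the other 3, which points to a structure of these 6 samples other than the siRNA.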

How the results depend on the processing

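Fits with 1 control library and with the GC trend removed were chosen after the data were seen, and all other alternatives were planned. Of the alternatives for the counts of changed genes and SLC40A1, 80 values stayed on their side or within 1.5 times, 63 counts moved by more and 10 values of SLC40A1 came to pass. Counts are given for siRNA 1, siRNA 2, between the siRNAs and shared. With no filter on low counts they were 1602 for siRNA 1, 86 between the siRNAs and 935 shared. DESeq2 gave 1495, 2020, 26 and 939, and voom gave 0 between the siRNAs, where edgeR gave 7 and 1407 genes had an unadjusted p under 0.05. Fits of 2 groups alone gave 112 for siRNA 1 and 97 shared. With the GC trend removed there were 949 for siRNA 1 and 616 shared. Against control library 3 alone there were 0 by edgeR for siRNA 1 (1753 at an unadjusted p under 0.05), 30 for siRNA 2 and 0 shared, against library 2 alone 296 for siRNA 1 and 250 shared, and against library 1 alone 808 for siRNA 2. An adjusted p under 0.01 left 28, 264, 1 and 25, and a fold of 2 or more 26, 34, 1 and 11. With an unadjusted p under 0.05 in 1 of the 2 comparisons, 1177 were shared. With 1 control library or 1 library left out there are fewer samples; otherwise the cause was not tested.

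SLC40A1 kept its direction against the control in each alternative that tested it; the filter at 1 CPM left it out. It passed with no filter (-1.06, adjusted p = 0.0136, and -0.94, adjusted p = 0.0316), with the GC trend removed (-1.08 and -0.96; adjusted p = 0.0429 and 0.0456) and, for siRNA 2, in the fit of 2 groups alone (-0.93, adjusted p = 0.0177). DESeq2 gave it no adjusted p (unadjusted 0.00207 and 0.00542). With 52 to 79 counts in the control libraries its depth limits what can be resolved. With 1 library left out its log2 fold change ran from -1.42 to -0.78 for siRNA 1, from -1.06 to -0.84 for siRNA 2 and from -0.15 to 0.49 between the siRNAs. The counts of changed genes then ran from 16 to 2987 for siRNA 1, from 167 to 2502 for siRNA 2, from 0 to 279 between the siRNAs (1108 and 1053 at an unadjusted p under 0.05 in the 2 edgeR fits with 0) and from 14 to 1552 shared.

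Replicate numbers do not pair the libraries by the labels: deviations correlated at -0.0177 to 0.147 for the same number and at -0.129 to 0.0536 for different numbers, and 7 of 9 libraries correlated best with their own number, a hint from the data only. With the replicate number as a block the counts were 2394, 2761, 117 and 1502, and SLC40A1 passed at -1.08 (adjusted p = 0.0137) and -0.94 (adjusted p = 0.0245).

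For gene lists 1131 values stayed on their side, 57 no longer passed and 34 came to pass. Of the 34, 3 came to pass with the GC trend removed and 4 with the replicate number as a block. A further 2 values turned in sign with 1 of the values past the threshold. Both turned for siRNA 1 against control library 3 alone: tumour-associated macrophage markers passed upward (adjusted p = 0.0497) and macrophage differentiation markers did not pass (0.840). For named genes 4365 values stayed, 1021 no longer passed and 255 came to pass, with 0 turned.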

Other observations

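The gene lists in the next 2 paragraphs, the tests on GC content, on the handling of the control libraries and on control library 3 alone, and the rule that 1 control library excludes nothing, were chosen only after the results were seen. Of 34 ribosome biogenesis genes tested, 4 rose with siRNA 1 (median log2 fold change 0.10, camera adjusted p = 7.00e-05; adjusted p = 0.198 with an estimated correlation; 4.22e-05 with the GC trend removed) and 9 with siRNA 2 (median 0.19, camera adjusted p = 4.91e-12; adjusted p = 0.0445 with an estimated correlation; 4.90e-13 with the GC trend removed). Nucleolin (NCL) rose by 0.24 ± 0.05 and 0.30 ± 0.05, and NOP56, of the box C/D particles that modify ribosomal RNA, by 0.23 ± 0.06 and 0.38 ± 0.06 (SE, n = 3 per group). Between the siRNAs this list was higher with siRNA 2 (median 0.10, camera adjusted p = 2.13e-06; adjusted p = 0.0765 with an estimated correlation; 1.70e-06 with the GC trend removed).

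Of 17 genes of fatty acid synthesis and desaturation tested, 4 fell with siRNA 1 (median -0.18, camera adjusted p = 3.34e-05; adjusted p = 0.272 with an estimated correlation; 4.22e-05 with the GC trend removed) and 8 with siRNA 2 (median -0.21, camera adjusted p = 2.65e-06; adjusted p = 0.243 with an estimated correlation; 5.95e-06 with the GC trend removed). The acetyl-CoA synthetase ACSS2 fell by 0.24 ± 0.05 and 0.35 ± 0.05, and the desaturase FADS2 by 0.34 ± 0.08 with each. Against control library 3 alone the medians of the fatty acid list were -0.10 and -0.12. Of 31 immediate early genes, ZFP36 alone fell with siRNA 1 (list median -0.09, camera adjusted p = 0.0469; adjusted p = 0.437 with an estimated correlation; 0.240 with the GC trend removed). With siRNA 2, 13 fell, among them KLF2, JUN (-0.26 ± 0.05) and JUND (-0.34 ± 0.07), with a median of -0.15 (camera adjusted p = 2.65e-06; adjusted p = 0.109 with an estimated correlation; 0.000109 with the GC trend removed). Between the siRNAs this list was lower with siRNA 2 (median -0.09, camera adjusted p = 2.42e-06; adjusted p = 0.0925 with an estimated correlation; 7.31e-06 with the GC trend removed). Against control library 3 alone the medians against the control were -0.02 and -0.12. This list was first weighed as a pattern of its own, against a difference of control libraries 1 and 2 from the rest. That test could not tell, and it was dropped after its result was seen. Left-out libraries were not run for these 3 lists.

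Both siRNAs changed 398 genes in the same direction, and 2 of 100 splits of the libraries gave as many, the highest other (592) with the 3 control libraries also on one side, so a random grouping was argued against. Noise of the shared control libraries was argued against as the whole cause. With each siRNA set against a different control library, the covariance of fold changes was 0.0198 to 0.0418 in the 6 pairings. It was 0.0386 and 0.0418 where the pair was control libraries 1 and 2, and 0.0198 to 0.0246 where control library 3 was in the pair. The GC trend of control libraries 1 and 2 was argued against as the whole cause, since 337 of the 398 genes (84.7%) passed with the same sign after it was removed. The shared count was 21, 14 and 1552 without control library 1, 2 or 3. A difference of control libraries 1 and 2 from the rest, beyond the GC trend, may therefore account for part of the pattern. Control libraries handled apart from the others could give the same pattern, and this cannot be told apart from an effect of the siRNAs, since 0 tags in the labels name a batch, date or run. An effect of silencing SLC40A1 stays open beside it and was not tested.

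Cholesterol synthesis genes were lower with both siRNAs, with medians of -0.18 and -0.26. With an estimated correlation neither list call passed by camera (adjusted p = 0.227 and 0.149). With fry, which does not set the list against the other genes, both passed (adjusted p = 0.0175 and 0.00548). With siRNA 1, edgeR called 0 members in 5 of the 9 fits with 1 library left out, where 13 to 19 had an unadjusted p under 0.05. The GC trend of control libraries 1 and 2 was argued against as the whole cause, since the medians were -0.17 and -0.27 after it was removed. Against control library 3 alone they were -0.12 and -0.17, with 23 and 21 of 24 members lower, but 1 library excludes nothing, so a difference of control libraries 1 and 2 from the rest may account for part of the pattern and cannot be told apart from an effect of the siRNAs. This pattern was found and tested on the same data, and an effect of silencing SLC40A1 was not tested.

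Among 7-mers in 3' UTRs, tested on fold changes with the GC trend removed, 2 passed with each siRNA against the control, all with lower genes. With siRNA 1 these were AGGGACA (z = -5.12, 1691 genes), which is not in the SLC40A1 transcript, and GGCCCCA (z = -4.69, 1876 genes), which is. With siRNA 2 they were CACACAC (z = -5.15, 2096 genes) and CCCCCCA (z = -4.70, 1754 genes), neither of them in that transcript, which holds 17.8% of the 7-mers. Of the markers of other cells, NCAM1 (410 CPM), CD4 (210 CPM) and PECAM1 (484 CPM) were abundant over all 9 libraries, as was the precursor marker SPN (185 CPM). All 9 libraries came from the THP-1 line, so these levels were not read as a sign of other cells. Those lists therefore tell little of other cells.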
